A study of Rattus norvegicus with 6 samples.

How the data were processed

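Single-cell RNA sequencing libraries of rat corpus cavernosum were analysed, 2 labelled normal and 4 labelled DMED. Per the labels' protocols, fresh tissue was washed to remove blood, minced, digested with collagenases I and IV, neutral protease and DNase, filtered and depleted of dead cells by magnetic sorting before BD Rhapsody library preparation. How diabetes was induced, its duration and the age of the animals are not given in the sources used here.

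Each library was deposited as 1 table of whole-number molecule counts per cell and gene. Per the file headers, the counts were made by the authors with the BD Rhapsody whole transcriptome pipeline 1.12.1 on the rat reference mRatBN7.2, with molecular identifiers corrected by recursive substitution (RSEC), intronic reads not excluded and refined cell calling on. The submitters' processing notes name Cell Ranger 3.1.0, which the headers do not, and build mRatBN7.2. Per the file headers, the number of cells was set by hand for DMED 2 (5649) and DMED 3 (12870) and not for the others. The headers also give the bead version as Enhanced V2 for both normal libraries and Enhanced for all 4 DMED libraries, with later processing dates for the normal libraries, so no fit with batch as a term can be had. No value of the deposited counts was negative or fractional. Gene symbols are those of the files, 24987 over the union of the libraries, and a gene absent from a file was taken as 0 there. Of 173 marker genes listed 161, and of 608 genes on lists 575, matched a symbol. Genes without a match, such as Prkg1 and Cldn5, were not analysed here. No coordinates are given because the gene table supplied is of another assembly than the files.

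Cells with 500 or more molecules, 250 or more genes and 25% or less of molecules from mitochondrial genes were used. Mitochondrial shares here and below count gene symbols that start with Mt- and leave out unnamed gene models of the mitochondrial genome. These models held 5.32% and 5.34% of molecules in the normal libraries and 10.03%, 9.01%, 6.10% and 6.67% in DMED 1 to 4. The molecule minimum removed 0 cells, the lowest totals in the files being 1055, 1036, 1656, 1125, 1595 and 1981 in normal 1, normal 2 and DMED 1 to 4. Scrublet in scanpy 1.11.5, with an expected doublet rate of 0.05, marked 0, 0, 2, 1, 0 and 1 cells with its automatic threshold, which was taken as a failure, and the 5% of cells with the highest scores in each library were removed instead. Used cells numbered 23620, 17486, 5046, 4477, 11738 and 3849, with a median of 11.6%, 11.2%, 12.1%, 14.5%, 10.0% and 10.9% mitochondrial molecules. All 66216 cells were clustered together without batch correction on log-normalised counts, with 2000 variable genes picked within libraries, 40 principal components, 20 neighbours and Leiden clustering at resolution 1 (leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, Python 3.11.15). Bead version and group coincide, so clusters can follow either.

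A marker counted as present in a cluster at 20 CPM or more, 25% or more of its level in the cluster with the second highest level and 5% or more of the highest. A cluster was named for the cell type with the largest share of markers present, if this share was 50% or more, led the next type by 10 percentage points, rested on 3 or more markers and no other type had more markers among the 10 genes with the largest fold over other cells. These thresholds were set after the data were seen, the markers before. Clusters left unnamed with Grem1 at 25% or more of its second highest cluster level formed the Grem1-high stromal class. Clusters found in each library alone, given the class of the nearest joint cluster over marker genes, placed 90.0% of cells in the same class. Cluster 17 in the smooth muscle class had 1 marker of another type and 2 of its own among its 10 leading genes.

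Molecules were summed per library and class, and a library entered with 20 or more cells of the class. Genes were filtered with filterByExpr, scaled by TMM and tested with edgeR 4.0.16 (glmQLFit with robust estimation, glmQLFTest) in R 4.3.3, DMED minus normal, each class on its own, with Benjamini-Hochberg adjustment at 0.05 within the class. Fold changes are log2, levels are CPM of the class sum in a library with its total scaled by the TMM factor, and errors are SDs between libraries unless called SE. For gene lists, 33 lists were fixed in advance, and those with 5 or more tested members were tested with camera (limma 3.58.1, preset correlation 0.01) on voom values, beside camera with an estimated correlation and fry. With an estimated correlation, lists whose estimate lay under the preset lost their calls too. A lost call alone therefore does not show that correlated genes made it. Fry tests whether the genes of a list move one way on balance and does not compare them with other genes. Shares were tested with edgeR on cell numbers with the used cells of a library as its size, beside an exact permutation test over the 15 splits. The difference of the change between 2 classes was tested with limma on the difference of log2 CPM within a library. For levels, the percent of the highest class compares the mean CPM with that of the class where the gene is highest, in the group where the gene is higher, because free RNA can give molecules of a gene to cells that do not express it. Limits for counts of 0 use 3 counts over the group and cover counting error only.

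The genes named follow a rule fixed before the data were examined. In each main class they are the 8 largest rises and 8 largest falls among genes past the threshold whose DMED libraries all lay beyond both normal libraries and whose higher group averaged 20 CPM or more, leaving out unnamed gene models, ribosomal and mitochondrial genes and markers of other classes. Of each called list the 3 members with the smallest p in its direction were added, and for each main class 3 to 5 genes were always reported. In the other classes the 3 largest rises and 3 largest falls are named. Levels in the text on erythroid and lymphatic endothelial cells, those used to name clusters and the percent of the highest class use CPM without TMM scaling. Grem1, Comp and Sox9 in the Grem1-high class, Acan in its clusters and the markers given for erythroid cells fall outside this rule and were chosen after their values were seen.

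Each test was run on simulated counts drawn from the means and library sizes of these classes. Gene counts took the dispersions of the class and were drawn independently between genes, while cell numbers took a dispersion set to 0.1. Of 100 genes changed 2-fold and 100 changed 4-fold, the test recovered 62% and 89% in fibroblasts (14322 genes), 54% and 87% in smooth muscle (10644), 38% and 86% in pericytes (9449), 47% and 95% in vascular endothelium (11652), 20% and 82% in macrophages (8820), 58% and 94% in Grem1-high cells (13586) and 20% and 75% in Schwann cells (6489). For differences between classes the shares were 19% and 82% between fibroblasts and smooth muscle (10535 genes), 13% and 77% between fibroblasts and endothelium (11474), and 13% and 70% between smooth muscle and endothelium (10166). By camera at the preset correlation, a list raised 2-fold was recovered in all 7 classes, while 2 of the other lists were also called in macrophages and 0 elsewhere. With independent genes this cannot vouch for lists whose genes move together, such as cytokines in fibroblasts (estimated correlation 0.51). A 4-fold change of share, tried for pericytes and macrophages only, was recovered in 96% of 100 draws. Libraries of a group differed well beyond sampling noise, with a chi-square per degree of freedom between 27.2 and 114, so none was counted as a copy of another.

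Alternatives fixed before the data were examined were DESeq2 size factors, no filter on low counts, DESeq2 1.42.0 and limma voom in place of edgeR, markers of other classes left out, a stricter cell filter (1000 or more molecules and 10% or less mitochondrial), doublets kept, class sums thinned to the smallest library, clusters found in each library alone, replicate number as a block, each library left out, and for shares TMM factors over classes. Chosen after seeing the data were a fit on a single cluster per class, shares outside the Grem1-high stromal and fibroblast classes, and leaving out genes under 10% of the highest class. The single cluster of a class was the one whose smallest library held the most cells. Figures were drawn with matplotlib 3.10.9.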

Results

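Cells of the corpus cavernosum, the erectile tissue of the penis, were profiled by single-cell RNA sequencing on the BD Rhapsody platform, which counts RNA molecules per cell through molecular identifiers. Tissue came from SD rats in 2 groups, 2 normal libraries and 4 libraries of diabetes mellitus erectile dysfunction (DMED). The series design implies 1 comparison, DMED against normal, made below for the make-up of the tissue and for gene expression within each cell class. The files held 29759 and 21199 cells in normal 1 and 2, and 5481, 5649, 12870 and 4107 cells in DMED 1 to 4. Their molecule totals were 117673348, 93629513, 30569665, 23931424, 68836047 and 25608469 in the same order. After filtering, 41106 normal and 25110 DMED cells were used, with a median per cell of 3618 and 3863 molecules in the normal libraries and 4662.5, 3798, 4383 and 5115 in DMED 1 to 4. The bead version and the date of primary processing followed the groups, so batch and group cannot be told apart in any comparison below. Nothing in the labels says that libraries of a group came from separate animals, so p-values measure only the spread between these libraries, which may be technical.

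Clustering gave 30 clusters, and 9 kinds of cell were named from markers chosen before the data were examined. Fibroblast-like cells (Pdgfra, Col1a1, Dcn) were the most numerous named class, with 18079 normal and 7992 DMED cells. Smooth muscle-like cells (Acta2, Myh11, Cnn1) numbered 2378 and 2011, pericyte-like cells (Rgs5, Kcnj8, Abcc9) 2539 and 644, vascular endothelial-like cells (Pecam1, Cdh5, Tie1) 5231 and 1804, and macrophage-like cells (C1qa, Csf1r, Mrc1) 1283 and 318. Schwann-like, lymphatic endothelial-like, neutrophil-like and erythroid-like cells were smaller classes. Clusters 1, 2 and 6 had the highest levels of Grem1, a bone morphogenetic protein antagonist, and Comp, a cartilage matrix protein, among the clusters, and did not reach the marker rule for any type. The cartilage genes Comp and Acan were among the 10 leading genes of clusters 1 and 2, and whether these cells are stromal or of cartilage or bone was not settled. The 3 clusters were joined after the data were seen as a class called Grem1-high stromal below, of 6799 normal and 11506 DMED cells. Cluster 16 held low-depth cells with fibroblast markers, cluster 23 lay within the margin between pericyte and smooth muscle markers, and cluster 29 tied between T and NK cell markers. Cluster 28 led with dendritic cell markers but had 1 marker of another type and 0 of its own among its 10 leading genes. These 4 stayed unnamed.

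The tissue make-up differed between the groups. Grem1-high stromal cells made up 16.3% ± 2.47 (SD, n = 2) of normal cells and 50.4% ± 12.5 (SD, n = 4) of DMED cells, a 3.098-fold higher share. Pericytes fell from 6.11% ± 0.683 to 2.29% ± 0.697, macrophages from 3.01% ± 1.03 to 1.02% ± 0.606, and Schwann cells from 2.26% ± 0.807 to 0.704% ± 0.182. Lymphatic endothelial cells, which carry Prox1, Ccl21 and Reln, numbered 1353 in the normal libraries and 2 in the DMED libraries. Cluster 28 held 245 normal cells and 0 DMED cells, where a count of 0 allows a share of up to 0.0119% and makes it at least 49.9-fold lower, and cluster 29 held 207 and 3 cells.

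In edgeR's quasi-likelihood test of cell numbers with Benjamini-Hochberg adjustment over the classes, the log2 ratio of DMED over normal was 1.63 (SE 0.52, adjusted p = 0.00513) for Grem1-high stromal cells and -1.41 (SE 0.47, adjusted p = 0.00653) for pericytes. It was -1.53 (SE 0.48, adjusted p = 0.00443) for macrophages and -1.66 (SE 0.48, adjusted p = 0.00250) for Schwann cells. It was -8.56 (SE 0.74, adjusted p = 2.41e-15) for lymphatic endothelial cells, -5.37 (SE 0.74, adjusted p = 6.66e-09) for cluster 29 and -3.23 (SE 0.51, adjusted p = 1.68e-07) for cluster 23. Neutrophils fell by 1.24 on the log2 scale (adjusted p = 0.0474), while erythroid cells rose from 0.0970% ± 0.0893 to 0.850% ± 0.399 (adjusted p = 9.55e-06), a call that ended with clusters found in each library alone (log2 ratio 0.13, adjusted p = 0.960). Levels in erythroid cells rest on normal 2 alone (28 cells) and on DMED 2 to 4 (54, 112 and 37 cells). Normal 1 (8 cells) and DMED 1 (14 cells) held too few to enter. In DMED 2 to 4 against normal 2, Hbb-b1 stood at 13040 against 192500 CPM and Col1a1 at 7683 against 4588 CPM. Comp stood at 1416 against 0 CPM, and none of these values was tested. Fibroblasts, at 44.8% ± 7.28 and 27.9% ± 10.5 (adjusted p = 0.169), and vascular endothelial cells, at 12.6% ± 1.11 and 7.77% ± 2.14 (adjusted p = 0.169), did not pass the test. Nor did smooth muscle cells, at 5.56% ± 2.17 and 7.25% ± 2.14 (adjusted p = 0.440), or cluster 16 (adjusted p = 0.0624). An exact permutation test of shares gave 0.0667, the smallest two-sided p that 15 splits allow, for all 10 classes that passed. Since the shares of a library sum to a whole, the test was repeated among cells outside the Grem1-high stromal and fibroblast classes, a choice made after seeing the data. There the smooth muscle share was higher in DMED (log2 ratio 1.25, adjusted p = 0.0214), and the pericyte (-0.58), macrophage (-0.70), Schwann (-0.87) and neutrophil (-0.46) ratios no longer passed. With TMM factors over classes the Grem1-high ratio was 2.28, and the pericyte (-0.82), macrophage (-0.997), Schwann (-1.04) and neutrophil (-0.78) calls ended. The stricter cell filter gave 3.11 for Grem1-high cells, ended the neutrophil call (-0.90) and turned cluster 16 to 3.04 (adjusted p = 0.000142). Clusters found in each library alone ended the calls of macrophages (-1.45), neutrophils (-1.93) and cluster 23 (-10.04, fitted over 0 DMED cells). The Grem1-high call ended without normal 1 (1.79) or normal 2 (1.48). So did the pericyte call (-1.29) and the macrophage call (-1.14) without normal 1 and the Schwann call (-1.25) without normal 2. The fibroblast share passed without DMED 3 (-0.93). The neutrophil call ended without normal 1 (-1.39), normal 2 (-1.12), DMED 1 (-0.94), DMED 2 (-1.05) or DMED 4 (-1.11), and cluster 16 passed without DMED 1 (-1.44). The erythroid ratio was 2.40 without normal 1 and 4.597 without normal 2. Without DMED 3 the ratio was -2.57 for neutrophils. The fitted ratios were then -8.80 for cluster 29 and -11.49 for lymphatic endothelial cells, over 0 cells in DMED 1, 2 and 4, so their size is not measured. Within the Grem1-high class itself, Grem1 (log2 change 0.26, adjusted p = 0.730), Comp (0.33, adjusted p = 0.274) and Sox9 (-0.07, adjusted p = 0.888) did not pass the test.

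**Figure D1:**
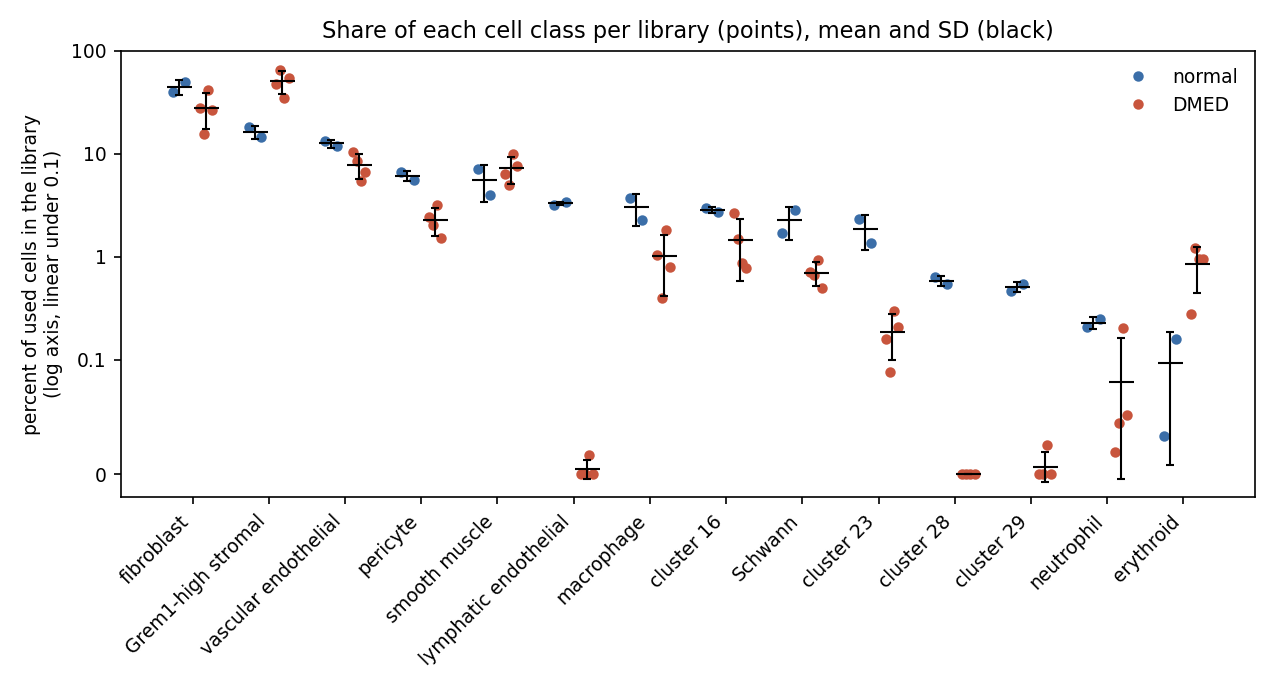
Share of used cells in each class, in percent on a log axis that is linear under 0.1, for each of the 2 normal (blue) and 4 DMED (red) libraries, with the group mean and SD in black. Grem1-high stromal cells average 50.4% in DMED against 16.3% in normal libraries, and cluster 28 lies at 0 in all 4 DMED libraries.

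In fibroblasts, 19 of 24 cytokines and NF-kB targets, 9 of 17 interferon response genes and 12 of 21 matrix remodelling enzymes fell in DMED. The calls of these 3 lists were lost with an estimated correlation (adjusted p = 0.588 for each) and kept with fry (adjusted p = 0.0267, 0.0239 and 0.0239). Of 14434 genes tested, 968 rose and 1573 fell. Different clusters held most of the class in the 2 groups, namely clusters 4, 5, 8, 14 and 19 in normal libraries and clusters 3, 7 and 12 in DMED libraries. The largest falls included Pi16, a marker of adventitial fibroblasts (576 ± 69.1 CPM, counts scaled to the total of the class, to 19.9 ± 15.8, log2 change -4.76, adjusted p = 0.0162). They also included Gpc3, a cell surface proteoglycan (271 ± 23.6 to 7.55 ± 3.59, -5.04, adjusted p = 0.000169), and Cck, the hormone cholecystokinin (41.1 ± 9.68 to 0.420 ± 0.187, -6.44, adjusted p = 6.61e-06). Inmt (-7.52), Mnda (-5.91), Sfrp5 (-5.68), Cmahp (-4.85) and Cyp2f4 (-4.30) completed the 8 largest falls, although Inmt differed widely between the normal libraries (55.0 ± 68.0 CPM) and Sfrp5 lay at 5.83% of its level in the highest class. Pi16 and Cyp2f4 were among the 10 leading genes of cluster 4, Gpc3 and Sfrp5 of cluster 24, and Cck of clusters 5 and 19. Cluster 4 held 1988 and 1868 cells in the normal libraries and 14, 0, 64 and 8 in DMED 1 to 4. Cluster 24 held 425 and 289 against 8, 6, 43 and 6. Cluster 5 held 1963 and 1825 against 27, 6, 93 and 7. The falls of these genes can therefore follow the mix of clusters in the class. The 8 largest rises were Gm15737 (3.96), Y_RNA (3.91), U2 (3.48), Anxa8 (3.38), H3f3c (2.83), Casr (2.76), Ankub1 (2.73) and U1 (2.62). Y_RNA, U1, U2 and H3f3c have near-identical copies in the genome, between which reads can be split, and are uncertain. Of the collagen and fibroblast genes followed throughout, Col3a1 fell from 11716 ± 2114 to 4548 ± 1852 CPM (-1.37, adjusted p = 0.0243) and the growth factor receptor Pdgfra from 374 ± 19.8 to 198 ± 38.0 (-0.92, adjusted p = 0.00641). Col1a1, at 42200 ± 11298 and 26102 ± 12281 CPM (adjusted p = 0.246), and Dcn, at 17009 ± 1044 and 20101 ± 4361 CPM (adjusted p = 0.4997), did not pass.

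Among gene lists, tested with limma's camera at a preset correlation and Benjamini-Hochberg adjustment, 8 were called in fibroblasts. Of 24 cytokines and NF-kB targets, 19 fell and 0 rose (22 fell when adjusted over the list alone), with Sod2 (-1.21), the apoptosis inhibitor Birc3 (-2.42) and the eosinophil chemokine Ccl11 (-4.69) leading, and the adjusted p of 4.36e-11 became 0.588 with an estimated correlation. Of 14 endothelial adhesion and activation genes, 8 fell (10 adjusted over the list alone), among them thrombomodulin, Thbd (-2.88), tissue factor, F3 (-2.23), and Ackr1 (-4.16, at 4.55% of the highest class). Its adjusted p was 0.588 with an estimated correlation. Interferon response genes fell in 9 of 17 (10 adjusted over the list alone), with Ifit3 (-3.85), Ifit2 (-2.43) and Ifitm3 (-1.21), and had an adjusted p of 0.588 with an estimated correlation. Matrix remodelling enzymes fell in 12 of 21 (12 fell and 1 rose adjusted over the list alone), with Loxl1, a collagen and elastin crosslinker (-1.91), Mmp14 (-1.49) and Ctsl (-0.90). Its adjusted p was 0.588 with an estimated correlation. Basement membrane genes fell in 4 of 14 (5 adjusted over the list alone), with Nid1 (-1.63), Lama2 (-1.11) and Col4a1 (-0.74). They had an adjusted p of 0.588 with an estimated correlation. In the antioxidant and NRF2 list 1 rose and 8 fell of 25, with Gstm1 (-1.43), Txnrd1 (-1.41) and Sod2, and in the complement list 1 rose and 6 fell of 16, with the C1 inhibitor Serping1 (-2.15), C1s (-1.11) and C1r (-0.65). Adjusted over the list alone these counts were 1 and 8, and 1 and 8, and both lists had an adjusted p of 0.772 with an estimated correlation. Heat shock genes went the other way, 7 rising and 1 falling of 13 (7 and 1 adjusted over the list alone), with Hspb1 (1.41), Hsp90aa1 (1.22) and Hspa8 (0.82), and had an adjusted p of 0.772 with an estimated correlation. Fry called the adhesion, interferon, matrix remodelling, basement membrane and antioxidant lists lower (adjusted p = 0.0239 each), and the cytokine list (0.0267). It did not call the complement (0.113) or heat shock (0.0808) lists.

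The number of fibroblast genes called was 1688 without DMED 1 and 1181 within cluster 7 alone, where 459 of the genes were also called. Cluster 7 was picked because its smallest library held the most cells, 321, although other fibroblast clusters held more in some libraries. Thbs4, Col11a2 and Tnmd were among its 10 leading genes, and it had Comp at 1233.5 CPM, against 16.5 CPM in cluster 4. The fit on cluster 7 therefore speaks for that cluster and not for the other fibroblasts. Within cluster 7, 595 rose and 586 fell, without the excess of falls seen in the whole class. Within that cluster the cytokine (adjusted p = 0.000436), adhesion (0.000376) and heat shock (0.00218) lists passed. The mitochondrially encoded (adjusted p = 0.000100), contractile (0.0110) and fatty acid (0.0438) lists were called lower there, which they were not in the whole class. There Sod2 (0.25), Nid1 (0.53), C1r (0.56), C1s (1.05), Ctsl (0.10), Mmp14 (0.71), Pdgfra (0.49) and Hspb1 (-0.49) had the opposite sign, and the matrix remodelling, basement membrane, interferon, antioxidant and complement lists did not pass. Markers of bone or cartilage cells moved with the group inside fibroblasts, with a median log2 change of 1.66 over 5 markers, of which 3 rose. Fibroblast markers themselves had a median of -1.14 over 10, of which 6 fell and 0 rose. Lymphatic markers moved with a median of -1.94 over 6, of which 5 fell, and vascular endothelial markers, beside the adhesion list, with a median of -1.05 over 11, of which 4 fell.

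In smooth muscle cells elastin, Fabp4 and Lpl fell and phosphodiesterase 5 rose, while Acta2 and Myh11 did not pass the test. Of 10790 genes tested, 214 rose and 210 fell. Cluster 17, with Cnn1, Actg2 and Mylk among its 10 leading genes, held 344 and 170 cells in the normal libraries. It held 79, 34, 658 and 89 cells in DMED 1 to 4. Cluster 9, the other cluster of the class, held 1330 and 534 against 245, 187, 514 and 205, so only DMED 3 had more cells in cluster 17. The median of molecules per cell moved with the group, at 3316 and 3678 in the normal libraries and 6047.5, 5748, 5735.5 and 5715.5 in DMED 1 to 4. Pde5a, which degrades cGMP and is the target of sildenafil, rose from 63.5 ± 2.14 to 109 ± 9.83 CPM (log2 change 0.78, SE 0.14, adjusted p = 0.0159, higher in 4 of 4 DMED libraries). The guanylate cyclase subunit Gucy1a1 (218 ± 20.2 and 163 ± 11.98 CPM, -0.42, adjusted p = 0.103) did not pass. Acta2 (10791 ± 745 and 9064 ± 861 CPM, -0.25, adjusted p = 0.371) and Myh11 (7017 ± 22.3 and 6257 ± 1203 CPM, -0.17, adjusted p = 0.689) did not pass either. Prkg1 was not analysed here. Eln, elastin, fell from 240 ± 96.2 to 28.7 ± 8.89 CPM (-3.01, adjusted p = 0.00369). The other large falls were Pmfbp1 (-4.23), the fatty acid binding protein Fabp4 (-3.94), Selp (-3.83, at 2.40% of the highest class), Rarres1 (-3.42), Fbln7 (-3.15), Tnfaip6 (-3.08, at 5.25% of the highest class) and Fmo2 (-2.80). Pmfbp1 and Rarres1 were among the 10 leading genes of pericyte cluster 13, and Fabp4 and Selp among those of vascular endothelial cluster 11. Pericyte markers within smooth muscle had a median log2 change of -0.27 over 9, of which 2 fell, and skeletal muscle markers -1.84 over 4, of which 1 fell. The largest rises were Ankub1 (4.40), Gm15737 (3.62), U2 (2.85), Cntnap5a (2.45), Oscp1 (2.44), Hmgb1 (2.37), H3f3c (2.36) and U1 (2.08), of which U1, U2, Hmgb1 and H3f3c are uncertain because of near-identical copies.

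In smooth muscle 12 lists were called. Of 26 fibrillar collagen and matrix genes 6 fell (7 adjusted over the list alone), with Eln, the matricellular genes Tnc (-2.52) and Sparc (-1.11), and the adjusted p was 0.560 with an estimated correlation. Fibroblast markers within smooth muscle had a median of -1.36 over 10, of which 1 fell, and Col1a1 stood at 1719 and 594 CPM there against 42200 and 26102 CPM in fibroblasts. Fatty acid and PPAR targets fell in 3 of 21, Fabp4, lipoprotein lipase Lpl (-2.16) and the carnitine palmitoyltransferase Cpt1a (-0.60). Basement membrane genes fell in 2 of 14, Col4a2 (-1.001) and Col18a1 (-0.99). The adjusted p was 0.276 for both with an estimated correlation. Adjusted over the list alone, 5 and 4 fell and 1 basement membrane gene rose. Lower lists with few called members were cytokines (1 of 17, Tnfaip3, -1.11, at 4.12% of the highest class; adjusted p = 0.341 with an estimated correlation) and endothelial adhesion (2 of 9, Selp and Thbd, -1.09; 0.320 likewise). Endothelial junction genes were lower too (2 of 10, Pecam1, -1.52, and Gja4, -0.95; 0.305 likewise), and the 3 lists had 6, 3 and 3 falls adjusted over the list alone. Pecam1 and Thbd lay at 2.02% and 3.14% of their levels in the highest class, and vascular endothelial markers within smooth muscle had a median log2 change of -1.52. Glycolysis and hypoxia genes rose in 5 of 22 (8 rose and 2 fell adjusted over the list alone), with Pfkl (0.91), Bnip3 (0.83) and Gapdh (0.77), and had an adjusted p of 0.320 with an estimated correlation. Cholesterol synthesis genes rose in 3 of 16 (5 adjusted over the list alone), Cyp51 (0.86), Insig1 (0.84) and Idi1 (0.83), with an adjusted p of 0.323 with an estimated correlation. Heat shock genes rose in 3 of 13 (12 adjusted over the list alone), Hsp90aa1 (1.10), Dnaja1 (1.09) and Hspa8 (0.78), with an adjusted p of 0.276 with an estimated correlation. The ER stress list rose in 1 of 17 (3 adjusted over the list alone), Ddit3 (0.81), and had an adjusted p of 0.276 with an estimated correlation. Immediate early genes, with Btg2 (0.94) the 1 of 19 that rose (4 rose and 1 fell adjusted over the list alone), and nuclear oxidative phosphorylation genes, 0 of 26, were called higher with adjusted p of 0.341 and 0.603 with an estimated correlation. Fry called the fatty acid and ER stress lists (adjusted p = 0.0121 each), and the basement membrane, junction, glycolysis and heat shock lists (0.0386 each). It did not call the collagen (0.238), cytokine (0.156), adhesion (0.0900), cholesterol (0.0900), immediate early (0.221) or oxidative phosphorylation (0.283) lists. The count of genes called fell to 78 without normal 1, 37 without normal 2, 192 without DMED 1 and 159 without DMED 4, and was 776 without DMED 3. Within cluster 9 alone it was 677 (446 rose and 231 fell), 288 of them shared, and the cytokine, adhesion, junction and oxidative phosphorylation lists did not pass. In that cluster camera at the preset correlation called the contractile list lower (adjusted p = 1.04e-13, against 0.165 in the whole class) and the cell cycle list higher (adjusted p = 0.00697).

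In pericytes, the mural cells of small vessels, 9 of 18 cytokines and NF-kB targets, 5 of 10 adhesion genes and 5 of 14 interferon response genes fell in DMED. The adjusted p of these 3 lists was 0.353 with an estimated correlation. Of 9469 genes tested, 264 rose and 367 fell, with most normal cells in cluster 13 and most DMED cells in cluster 22. The median mitochondrial share was 8.75% and 9.16% in the normal libraries and 11.5%, 12.1%, 9.97% and 10.2% in DMED 1 to 4. Rgs5 (1363 ± 34.2 and 1856 ± 359 CPM, adjusted p = 0.242), Notch3 (adjusted p = 0.471) and Pdgfrb (adjusted p = 0.602) did not pass. Il13ra2, a decoy receptor for interleukin 13, fell from 110 ± 2.36 to 0.525 ± 1.05 CPM (log2 change -6.42, adjusted p = 8.79e-08), and Cxcl9, an interferon-induced chemokine, from 431 ± 329 to 22.9 ± 16.9 (-3.89, adjusted p = 0.0398). Further large falls were Akr1c15 (-5.45), Adgrd1 (-4.95), Dapk2 (-3.99), Mnda (-3.96), Arntl2 (-3.38) and Bhlhe22 (-3.35). Smoc2, a secreted matrix-associated protein, rose from 47.4 ± 6.68 to 344 ± 57.2 CPM (2.85, adjusted p = 7.63e-07). Kctd16 rose from 14.1 ± 8.59 to 127 ± 51.8 (3.15, adjusted p = 0.00136), together with Epdr1 (2.80), Gm15737 (3.20) and the multi-copy U2 (4.16), 5S_rRNA (4.02), Y_RNA (3.04) and H3f3c (2.88), the last 4 uncertain for shared reads.

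Of the 6 lists called in pericytes, cytokines and NF-kB targets fell in 9 of 18 (14 adjusted over the list alone), with Csf1 (-1.59), Sod2 (-1.30) and Cxcl2 (-2.80, at 0.190% of the highest class), and had an adjusted p of 0.353 with an estimated correlation. Adhesion genes fell in 5 of 10 (5 adjusted over the list alone), with the protein C receptor Procr (3570 ± 634 to 839 ± 374 CPM, -2.09), Thbd (-2.06) and Vcam1 (-1.53). Interferon response genes fell in 5 of 14 (6 adjusted over the list alone), with Ifit3 (-2.77), Ifit1 (-2.69) and Ifit2 (-1.58). Fatty acid and PPAR targets fell in 3 of 18 (4 adjusted over the list alone), Fabp4 (-2.32), Angptl4 (-2.27) and Lpl (-1.83). All 3 had an adjusted p of 0.353 with an estimated correlation. Vascular endothelial markers in pericytes had a median of -1.18 over 7, of which 2 fell, and lymphatic markers -3.15 over 3, of which 2 fell. Contractile genes fell in 3 of 19 (4 adjusted over the list alone), Tpm1 (-0.97), Synpo2 (-0.92) and Acta2 (-0.87), with an adjusted p of 0.819 with an estimated correlation. Smooth muscle markers within pericytes had a median of -0.45 over 10, of which 2 fell, and fibroblast markers -0.29 over 9, of which 3 fell. Heat shock genes rose in 5 of 13 (8 adjusted over the list alone), with Hspb1 (1.19), Hsph1 (0.97) and Hsp90aa1 (0.87), and an adjusted p of 0.353 with an estimated correlation. Within cluster 22 alone 33 genes were called (25 rose and 8 fell), 28 of them shared, the cytokine (adjusted p = 0.0159) and heat shock lists passed, and the glycolysis list was called higher (adjusted p = 0.0214). The other lists called in the class did not pass, and Tpm1 (0.15), Csf1 (0.02), Vcam1 (0.40) and Fabp4 (0.52) had the opposite sign. The count was 370 without normal 1 and 293 without normal 2.

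Vascular endothelial cells had lower Kdr, the main VEGF receptor, at 318 ± 12.2 in normal and 189 ± 29.4 CPM in DMED libraries (log2 change -0.74, SE 0.15, adjusted p = 0.0290). Nos3, the endothelial nitric oxide synthase, stood at 200 ± 5.61 and 183 ± 15.4 CPM (-0.13, adjusted p = 0.656) and Vwf at 186 ± 52.4 and 118 ± 44.98 (-0.65, adjusted p = 0.376), and neither passed. Cldn5 was not analysed here. Of 11692 genes tested, 245 rose and 240 fell, with most DMED cells in cluster 10 and normal cells spread over clusters 10, 11, 20 and 21. The largest falls were Apod (-4.10, at 2.03% of the highest class), Gfpt2 (-2.29, at 8.85%), Cyp4b1 (-2.25), Papln (-1.99), the protease inhibitor Timp4 (-1.95), Tmem41a (-1.91), Rgs20 (-1.81) and Lrg1 (540 ± 216 to 155 ± 47.3 CPM, -1.79, adjusted p = 0.0295). Lrg1 was among the 10 leading genes of cluster 21, which held 484 and 406 cells in the normal libraries and 49, 34, 16 and 14 in DMED 1 to 4. Its fall can therefore follow the mix of clusters in the class. The largest rises were Ankub1 (3.73), Dcdc2c (3.50), Gm15737 (3.45), Oscp1 (2.57) and the multi-copy Y_RNA (3.30), U1 (3.19), 5S_rRNA (3.01) and U2 (2.95), the last 4 uncertain.

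Of the 7 lists called in endothelium, immediate early genes rose in 4 of 19 (9 rose and 2 fell adjusted over the list alone), with Egr1 (726 ± 86.3 to 1625 ± 296 CPM, 1.16, adjusted p = 0.0126), Egr2 (0.79) and Klf4 (0.70). Glycolysis and hypoxia genes rose in 3 of 22 (6 rose and 1 fell adjusted over the list alone), Gapdh (1.09), Tpi1 (1.05) and Pkm (1.02). Heat shock genes rose in 5 of 13 (9 adjusted over the list alone), with Hsph1 (1.44), Dnaja1 (0.90) and Hspa8 (0.75). All 3 had an adjusted p of 0.795 with an estimated correlation. Cytokines and NF-kB targets fell in 5 of 20 (7 adjusted over the list alone), with Birc3 (-1.65), Csf1 (-0.88) and Il1b (-5.39, at 0.0473% of the highest class). Complement genes fell in 1 of 14 (1 adjusted over the list alone), Cd55 (-1.50). Both lists had an adjusted p of 0.795 with an estimated correlation. Adhesion genes were called lower with 0 of 14 passing singly (2 adjusted over the list alone), Vcam1 standing at -2.04 (adjusted p = 0.0712) and Selp at -1.78 (adjusted p = 0.208), and contractile genes were called higher with 0 of 19 passing (0 adjusted over the list alone). Both had an adjusted p of 0.795 with an estimated correlation, and the contractile members named by the rule, Casq2, Tpm2 and Cnn1, lay at 3.58%, 4.79% and 1.05% of the highest class. Selp was among the 10 leading genes of cluster 11, which held 1329 and 903 cells in the normal libraries and 53, 16, 101 and 74 in DMED 1 to 4. Its value can therefore follow the mix of clusters. Lymphatic markers in endothelium had a median of -1.52 over 5, of which 1 fell. Smooth muscle markers there had a median log2 change of 0.69 over 10, of which 0 rose by edgeR's test, pericyte markers 0.81 over 9, of which 1 rose, and bone or cartilage markers 1.85 over 5, of which 0 rose. The count of genes was 79 without normal 1, 6 without normal 2, 192 without DMED 1, 168 without DMED 2 and 765 without DMED 3. Under a stricter cell filter it was 241 and the contractile list had a median of -0.32, and within cluster 10 alone, with 370 genes called and 243 shared, the immediate early and complement lists did not pass. There the junction list was called lower (adjusted p = 0.000297), and the antioxidant (0.0351), oxidative phosphorylation (0.00686) and ER stress (0.00405) lists higher.

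In macrophages Il1b fell from 4247 ± 989 (SD, n = 2) to 263 ± 94.6 CPM (SD, n = 3; log2 change -4.01, SE 0.31, adjusted p = 0.000409). Tnf fell from 1003 ± 17.2 to 162 ± 28.2 (-2.60, adjusted p = 0.000409) and the chemokine Ccl3 from 3715 ± 1358 to 321 ± 112 (-3.50, adjusted p = 0.000891). DMED 2, with under 20 macrophages, did not enter. The normal libraries held 883 and 400 macrophages and DMED 1, 3 and 4 held 53, 216 and 31. The DMED sums were 369149, 1187514 and 130204 molecules, so low levels there rest on few molecules. The median mitochondrial share was 10.3% and 9.38% in the normal libraries and 12.3%, 11.6% and 12.3% in DMED 1, 3 and 4. Of 8734 genes tested, 121 rose and 238 fell. The mannose receptor Mrc1 fell from 2483 ± 859 to 744 ± 217 CPM (-1.74, adjusted p = 0.0103), whereas C1qa (1466 ± 172 and 1182 ± 325 CPM, adjusted p = 0.562) and Cd163 (1096 ± 506 and 136 ± 121 CPM, -2.92, adjusted p = 0.25004) did not pass. Siglec10 and Cryga had 0 counts in the DMED macrophages, at least 15.9-fold and 15.2-fold lower against the limit of 3 counts over the group. Other large falls were Cd38 (-5.74), Siglec5 (-5.74), Ifit3 (-5.24), Dnase1l3 (-5.01), Lif (-4.64) and Il1a (-4.61). The largest rises were Gm15737 (4.42), Lilrb3l (4.36), Diaph3 (3.68), Ankub1 (3.29), complement C3 (3.28), Oscp1 (3.19), H3f3c (3.103, uncertain) and Larp6 (3.002).

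Of the 10 lists called in macrophages, cytokines and NF-kB targets fell in 15 of 23 (22 adjusted over the list alone), with a median log2 change of -2.07. MHC class II genes, which present antigen, fell in 4 of 7 (5 adjusted over the list alone), with RT1-Da (-2.11), RT1-Ba (-1.81) and Cd74 (9989 ± 4041 to 3450 ± 659 CPM, -1.53). Resident macrophage genes fell in 3 of 11 (5 adjusted over the list alone), Mrc1, Maf (-1.50) and Pf4 (-1.49). The adjusted p of all 3 was 0.452 with an estimated correlation. Interferon response genes fell in 3 of 15 (5 adjusted over the list alone), Ifit3, Oasl (-3.02) and Gbp2 (-1.97), with an adjusted p of 0.498 with an estimated correlation. Adhesion genes fell in 2 of 11 (4 adjusted over the list alone), Vcam1 (-3.04, at 7.66% of the highest class) and Thbd (-1.91), while vascular endothelial markers had a median of -1.07 over 8, of which 2 fell. Lymphatic markers within macrophages had a median of -2.85 over 3, of which 1 fell. VEGF, angiopoietin and Notch genes fell in 1 of 11 (2 adjusted over the list alone), Notch1 (-1.41). Both lists had 0.452 as the adjusted p with an estimated correlation. Cell cycle genes rose in 4 of 12 (7 adjusted over the list alone), with Cenpf (4.96), Top2a (4.38) and Mki67 (3.71), at low levels such as 3.15 ± 0.952 and 39.2 ± 41.2 CPM for Mki67, and an adjusted p of 0.498 with an estimated correlation. Heat shock genes rose in 1 of 13 (9 adjusted over the list alone), Hspb1 (1.96), with an adjusted p of 0.373 with an estimated correlation. Nuclear oxidative phosphorylation genes (0 of 26 passing, 0 adjusted over the list alone) and the NADPH oxidase and RAGE ligand list (0 rose and 1 fell of 12; 6 rose and 2 fell adjusted over the list alone), with S100a6 at 1.58 (adjusted p = 0.0604) and S100a4 at 1.09 (adjusted p = 0.0551), were called higher, with adjusted p of 0.498 and 0.452 with an estimated correlation. The count of genes was 225 without normal 1, 66 without normal 2 and 114 without DMED 4.

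**Figure D2:**
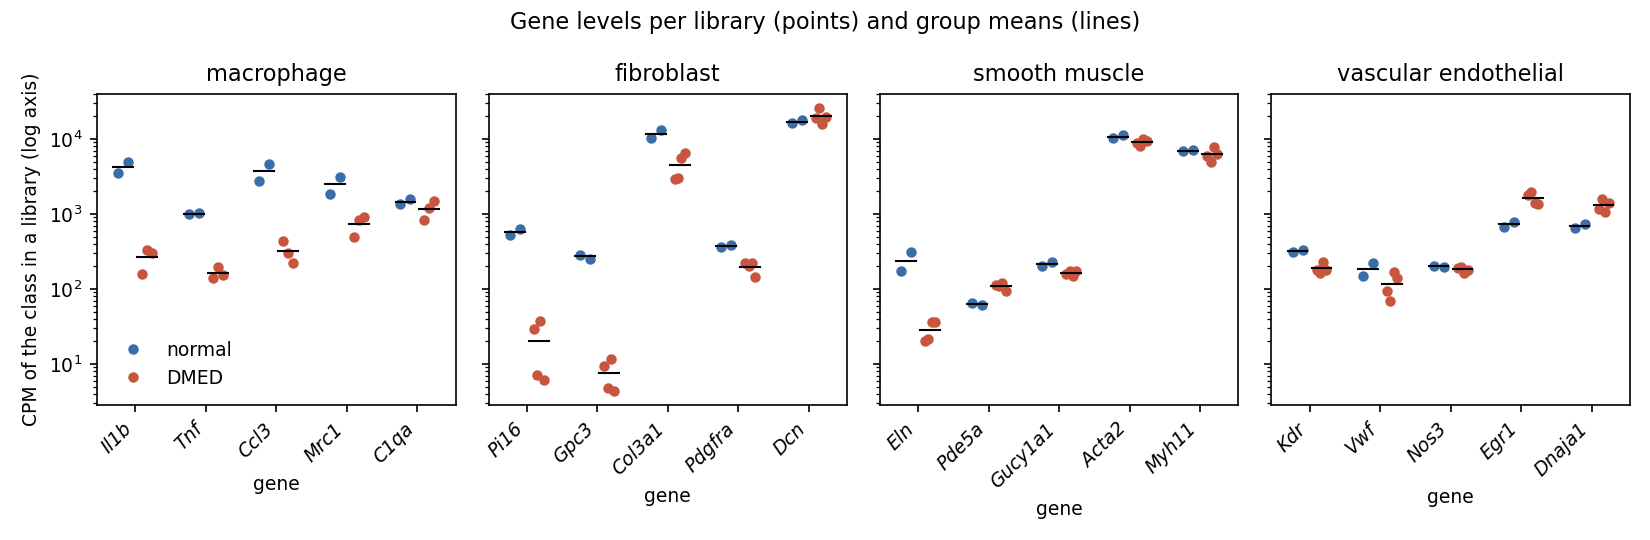
Level of selected genes in 4 cell classes, in CPM of the class on a log axis, for each normal (blue) and DMED (red) library, with the group means as lines. In macrophages Il1b lies at a mean of 4247 CPM in normal and 263 CPM in DMED libraries, while Nos3 in vascular endothelium lies at 200 and 183 CPM.

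Grem1-high stromal cells and Schwann cells were examined more briefly. In Grem1-high cells 453 of 13613 genes rose and 494 fell. Normal cells of the class lay mostly in clusters 1 and 6 and DMED cells mostly in clusters 1 and 2. Its median mitochondrial share was 16.2% and 17.2% in the normal libraries and 12.9%, 15.2%, 11.1% and 11.5% in DMED 1 to 4, and its median of molecules 3033 and 2683.5 against 4326.5, 3671, 3998 and 4928. Il6 (-2.95, adjusted p = 0.00897), Apod (-2.99) and Selp (-3.49) had the largest falls, all under 3% of their levels in the highest class, and Gm15737 (3.65) and Ankub1 (3.46) the largest rises. Y_RNA also rose, but leads cluster 2 of this class and is therefore not read as a result. Vascular endothelial markers fell in 9 of 11 within this class, with a median log2 change of -1.73. The median was -1.33 for Schwann markers (2 of 7 fell), -1.21 for macrophage markers (0 of 7 by edgeR's test), -0.86 for smooth muscle markers (1 of 10 rose) and -2.28 for lymphatic markers (3 of 6 fell). Its 11 called lists were lower for cytokines (5 of 23 fell), adhesion (4 of 14), VEGF and Notch (6 of 19), interferon (3 of 15), and MHC class II (1 of 5). They were lower as well for Schwann myelin (2 of 8), contractile (1 rose and 0 fell of 19), resident macrophage (0 of 10) and immediate early genes (0 of 19), and higher for heat shock (5 of 13 rose) and oxidative phosphorylation (4 of 26 rose). Adjusted over the list alone, 8, 10, 7, 4, 4, 4, 2, 0 and 0 members of the lower lists fell, 1 contractile gene rose, and 7 and 5 members of the higher lists rose. The immediate early list was called higher (median 0.21, adjusted p = 0.00996) with clusters found in each library alone, and the oxidative phosphorylation list had a median of -0.01978 in cluster 1 alone. There the junction (adjusted p = 0.0349) and glucocorticoid response (0.0419) lists were called lower as well. All 11 lists had an adjusted p of 0.792 with an estimated correlation. The count of genes called was 28 without normal 1, 53 without normal 2, 98 without DMED 1, 326 without DMED 2, 2703 without DMED 3 and 103 without DMED 4.

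In Schwann cells, the glia of peripheral nerve, 8 of 6550 genes rose and 5 fell, with DMED 4 left out for having under 20 cells. The median of molecules per cell was 2335 and 2401 in the normal libraries and 3872.5, 2924 and 3082 in DMED 1 to 3. Igsf10 (3.08), Myoc, myocilin (2.60), and Oscp1 (2.27) rose, and Apod (-2.90, at 2.96% of the highest class), Pex5l (-2.45) and Apoe (895 ± 272 to 185 ± 82.2 CPM, -2.29, adjusted p = 0.0148) fell. Of the 9 lists called, cytokines, adhesion, interferon, cholesterol synthesis and glucocorticoid response genes were lower and collagen, TGF-beta, mitochondrially encoded and heat shock genes higher, with 1 single member passing, in the TGF-beta list. Adjusted over the list alone, 4, 3, 3, 2 and 2 members of the lower lists fell and 3, 1, 1 and 5 of the higher lists rose. Their adjusted p lay between 0.281 and 0.734 with an estimated correlation. The count of genes was 48 without normal 1, 4 without DMED 2, and 1 without DMED 1 or DMED 3.

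**Figure D3:**
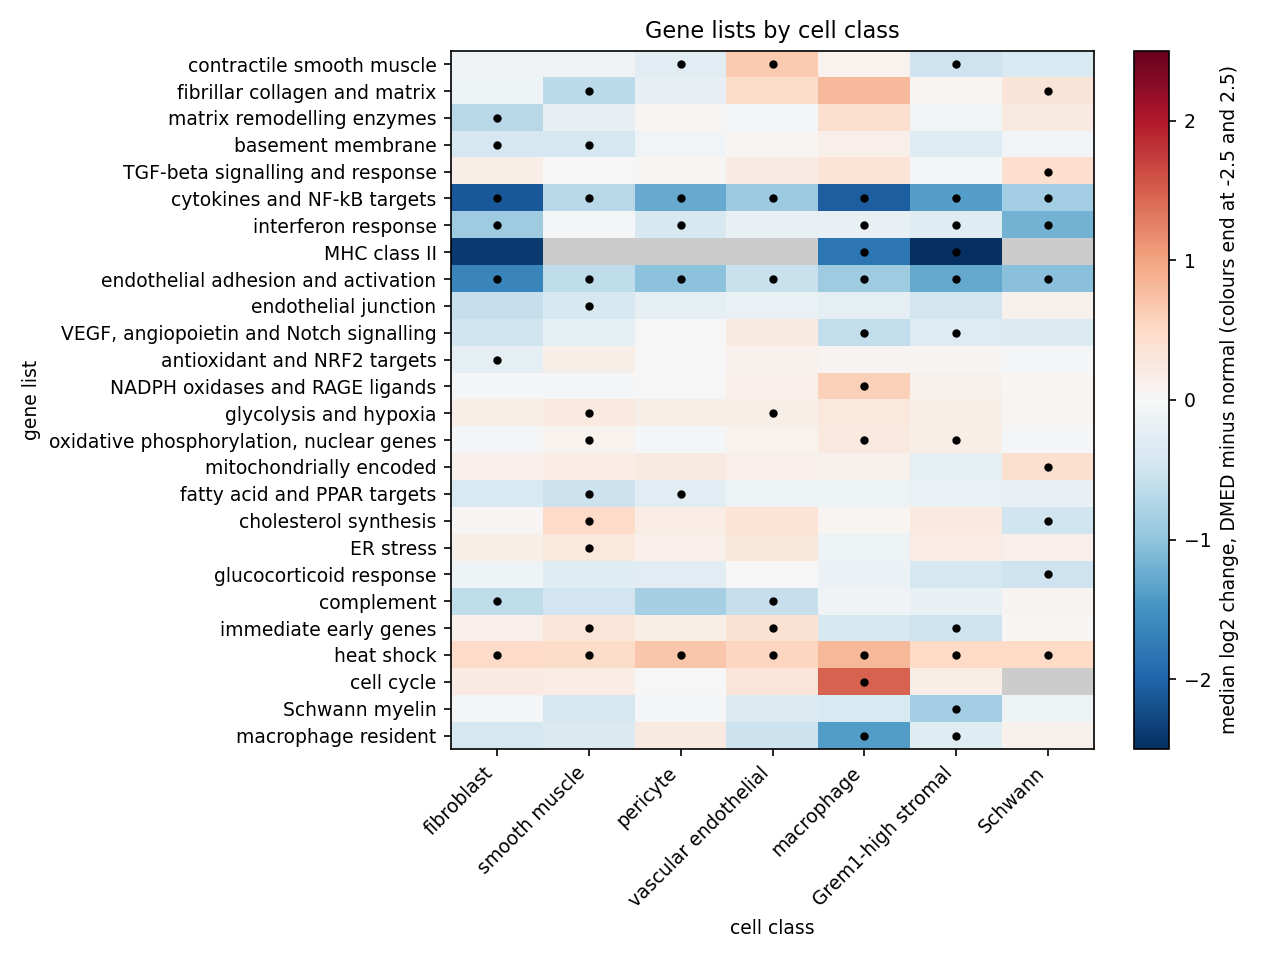
Median log2 change from normal to DMED of each gene list (vertical) in each tested cell class (horizontal), with blue for lower and red for higher in DMED, colours ending at -2.5 and 2.5, grey for lists not tested and a dot where camera with the preset correlation called the list. Cytokines and NF-kB targets carry a dot on blue in all 7 classes, with a median of -2.12 in fibroblasts, and had adjusted p between 0.281 and 0.795 with an estimated correlation.

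The nitric oxide and cGMP list, the RhoA, endothelin and adrenergic list, the p53, apoptosis and senescence list, the insulin and IGF list, the Schwann repair list and the inflammatory and lipid macrophage list were not called by camera at the preset correlation in any class tested, with smallest adjusted p of 0.0740, 0.165, 0.223, 0.106, 0.163 and 0.0979 over the classes. Fry called the RhoA, endothelin and adrenergic list lower in smooth muscle (adjusted p = 0.0386) and the p53, apoptosis and senescence list lower in fibroblasts (adjusted p = 0.0239). For nitric oxide and cGMP signalling, 1 rose and 0 fell of 11 in smooth muscle (1 and 1 adjusted over the list alone, list adjusted p = 0.769) and 0 passed of 13 in vascular endothelium (0 adjusted over the list alone, list adjusted p = 0.310). Haemoglobin genes had too few tested members in every class for a list test.

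The change between groups was itself compared between classes with limma on the difference within each library. Between fibroblasts and smooth muscle it differed for 409 of 10703 genes, among them F3 (difference of log2 changes -2.45, adjusted p = 0.00454), Thbd (-1.85, adjusted p = 0.00454), Gstm1 (-1.58, adjusted p = 0.00695) and Nid1 (-1.23, adjusted p = 0.00793), lower in fibroblasts. For Tnc the difference was higher in fibroblasts (3.45, adjusted p = 0.00555). Nid1 had a log2 change of 0.53 in fibroblasts of cluster 7 alone, the opposite sign, so its difference can follow the mix of clusters. Between fibroblasts and vascular endothelium the change differed for 50 of 11532 genes, including Thbd (-3.04, adjusted p = 0.0177), Ifit2 (-2.71, adjusted p = 0.0280) and Hsph1 (-1.32, adjusted p = 0.0360). Between smooth muscle and vascular endothelium it differed for 7 of 10286, none of them among the genes named above. For fibroblasts and smooth muscle the count was 29 without normal 1, 149 without DMED 1, 670 without DMED 3 and 101 without DMED 4. Without normal 2 limma called 0, with 895 genes at an unadjusted p under 0.05. For fibroblasts and endothelium it was 4 without normal 1, 2 without normal 2, 12 without DMED 1, 159 without DMED 3 and 18 without DMED 4. Without DMED 2 limma called 0, with 1615 at an unadjusted p under 0.05. For smooth muscle and endothelium it was 17 without normal 1, 18 without DMED 3 and 26 without DMED 4. Without normal 2 or DMED 1 limma called 0, with 413 and 1141 at an unadjusted p under 0.05.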

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

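Of the tests of explanations in this part, only the one on lymphatic markers was chosen before its result was seen. A total of 195 sets of 4 DMED values were screened for a library far from the other 3, and chance alone would pick out about 9.75 of them. The sets with such a library were 14, of which those with the other 3 libraries at 0 follow from any count above 0 and show no difference between libraries. The screen picked DMED 3 for its share of lymphatic endothelial cells (0.0170%) and of cluster 29 (0.0256%), with 0 cells in the other DMED libraries, where 0 cells allow 0.0595%, 0.0670% and 0.0779%. It also picked DMED 3 for Lpl in smooth muscle (21.0 CPM, low), for Y_RNA (11.6 CPM, low), Adgrd1 (1.05 CPM), Akr1c15 (1.05 CPM) and Il13ra2 (2.10 CPM) in pericytes, the last 3 at 0 in the other DMED libraries, and for Gm15737 (18.8 CPM, low), Cyp4b1 (4.41 CPM, low) and Il1b (0.232 CPM, the other DMED libraries at 0) in vascular endothelium. DMED 2 stood apart with Ifit3 at 0 CPM in pericytes and Tmem41a at 7.02 CPM in endothelium, and DMED 4 with C4a at 28.2 CPM and Tpi1 at 189 CPM in endothelium. DMED 3 holds the most cells of the DMED group, 11738 used.

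The change from normal to DMED differed between cell classes for 409 genes between fibroblasts and smooth muscle, 50 between fibroblasts and vascular endothelium, and 7 between smooth muscle and vascular endothelium, by limma's test of the difference itself. At an unadjusted p under 0.05 the numbers were 2024, 1709 and 1202.

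Lymphatic endothelial cells, cluster 28 and cluster 29 were nearly missing from the DMED libraries. Cells with 3 or more lymphatic markers in any class had a DMED share that was 1.26% of the normal share, which argues against lymphatic cells having been placed in other classes. The DMED files have higher molecule floors, yet 81.7% of the normal cells of these 3 clusters lay above the highest of them, 1981 molecules, which argues against that floor as the whole cause. Differences in tissue sampling, dissociation or beads stay open, since 0 DMED libraries were made on the bead version of the normal libraries, and a biological loss in DMED is untested for the same reason.

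Cytokines and NF-kB targets were called lower in DMED in all 7 tested classes by camera at the preset correlation, with adjusted p between 0.281 and 0.795 with an estimated correlation, and by fry only in fibroblasts (adjusted p = 0.0267). In fibroblasts the 16 members at 10% or more of the highest class had a median log2 change of -1.90, which argues against free RNA from other classes as the cause there; this was not tested in the other classes. At the preset correlation, fits on a single cluster called the list lower in 4 of the 5 classes made of several clusters that could be fitted, which argues against a shift between clusters as the whole cause. The heat shock list was called higher, not lower, in DMED in 7 of 7 classes at the same correlation. This argues against stronger handling stress in the normal libraries only as far as that list measures it. Its adjusted p was 0.276 to 0.795 with an estimated correlation, and fry called it only in smooth muscle and Schwann cells. Camera at the preset correlation called immediate early genes lower in Grem1-high cells (adjusted p = 0.0184, and 0.792 with an estimated correlation). With clusters found in each library alone it called them higher there (adjusted p = 0.00996). It also called them higher in smooth muscle (adjusted p = 0.00449, and 0.341 with an estimated correlation) and vascular endothelium (0.00114, and 0.795 likewise). The bead version and date, which coincide with the groups, and a biological difference stay open.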

How the results depend on the processing

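The fits on a single cluster, the shares outside 2 classes and the fits without genes under 10% of the highest class were chosen after seeing the data. Of 4788 values of named genes and lists under alternatives, 4015 kept direction and side of the threshold, 655 kept direction but were no longer called, 100 were newly called and 18 had the other direction. Left-out fits with 1 normal library assume that it varies like the DMED libraries. The stricter cell filter left too few libraries with 20 cells for smooth muscle, macrophages, Schwann cells and the differences with smooth muscle, so no value is given there. The cause of each change below was not tested, except that thinned sums and left-out libraries hold fewer molecules or samples by construction.

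Gene counts moved as follows. Without the filter on low counts 927 genes were called in smooth muscle (424 as reported), 981 in pericytes (631), 1591 in vascular endothelium (485), 808 in macrophages (359) and 193 in Schwann cells (13). DESeq2 called 815 in endothelium, 1568 in Grem1-high cells (947) and 40 in Schwann cells, and voom 80 in Schwann cells. The stricter cell filter gave 241 in endothelium and 255 in Grem1-high cells, clusters found in each library alone 607 in Grem1-high cells, and thinning 308 in pericytes, 220 in macrophages and 7 in Schwann cells. With doublets kept, edgeR called 0 in Schwann cells, with 619 at an unadjusted p under 0.05. Single clusters gave 1181 in fibroblasts (2541), 677 in smooth muscle, 33 in pericytes and 514 in Grem1-high cells. Leaving out 1 library gave 725 to 3128 in fibroblasts, 37 to 776 in smooth muscle, 293 to 623 in pericytes, 6 to 765 in endothelium, 66 to 382 in macrophages, 28 to 2703 in Grem1-high cells and 1 to 48 in Schwann cells. Differences between classes ranged over 0 to 670 genes between fibroblasts and smooth muscle and 0 to 159 between fibroblasts and endothelium (12 under the stricter filter). Between smooth muscle and endothelium the range was 0 to 26 (4 without the filter on low counts, 67 with single clusters). The counts of 0 came from limma, with 895, 1615, 413 and 1141 genes at an unadjusted p under 0.05.

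Lists called without the filter on low counts numbered 16 in fibroblasts (8 as reported), 19 in smooth muscle (12) and 14 in pericytes (6). With an estimated correlation camera called 0 in all 7 classes, among them lists whose estimate lay under the preset 0.01. In smooth muscle the ER stress list (estimated correlation -0.0332) went from an adjusted p of 0.00813 to 0.276. The junction list there (-0.0316) went from 0.0211 to 0.305. Such losses cannot be put down to genes that move together. Fry called 0 in pericytes, endothelium, macrophages and Grem1-high cells and 2 in Schwann cells. Thinning gave 10 in pericytes, 6 in macrophages (10) and 4 in Schwann cells (9), and the single cluster 3 in pericytes. Leaving out 1 library gave 7 to 11 in fibroblasts, 11 to 19 in smooth muscle, 6 to 9 in pericytes, 5 to 9 in endothelium, 8 to 14 in macrophages, 9 to 13 in Grem1-high cells and 7 to 9 in Schwann cells.

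Log2 ratios of shares that no longer passed were, with TMM factors over classes, -1.04 for Schwann cells, -0.997 for macrophages, -0.78 for neutrophils and -0.82 for pericytes. With clusters found in each library alone they were -10.04 for cluster 23 (fitted over 0 DMED cells), 0.13 for erythroid cells, -1.45 for macrophages and -1.93 for neutrophils. Outside the Grem1-high stromal and fibroblast classes they were -0.87 for Schwann cells, -0.70 for macrophages, -0.46 for neutrophils and -0.58 for pericytes, and smooth muscle passed at 1.25. The stricter filter gave -0.90 for neutrophils, no longer passing, and 3.04 for cluster 16, the other direction, while cluster 16 passed at -1.02 with doublets kept. Under the exact permutation test 10 calls did not pass at the ratios 1.63, -1.66, -3.23, -9.03, -5.37, 3.15, -8.56, -1.53, -1.24 and -1.41. The -9.03 is a fitted value for cluster 28, which had 0 DMED cells, where only a share at least 49.9-fold lower can be stated. Leaving out 1 library gave 1.48 to 1.79 for Grem1-high cells, -1.99 to -1.25 for Schwann cells, -1.44 to -0.76 for cluster 16, -0.93 to -0.48 for fibroblasts, -1.997 to -1.14 for macrophages, -2.57 to -0.94 for neutrophils and -1.61 to -1.26 for pericytes.

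Values with the other direction in single clusters were, in fibroblasts, Sod2 0.25, Nid1 0.53, C1r 0.56, C1s 1.05, Hspb1 -0.49, Ctsl 0.10, Mmp14 0.71, Pdgfra 0.49, and the medians of the matrix remodelling (0.10) and complement (-0.01161) lists. In pericytes they were Tpm1 0.15, Csf1 0.02295, Vcam1 0.40, Fabp4 0.52 and the contractile list (-0.03773), and in Grem1-high cells the oxidative phosphorylation list (-0.01978). The contractile list in endothelium was -0.32 under the stricter filter, and the immediate early list in Grem1-high cells 0.21 with clusters found in each library alone.

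Only the numbers 1 and 2 are shared between groups and nothing in the labels pairs the libraries, so no pairing is taken from the numbers. Deviations of equal-numbered libraries correlated between -0.112 and 0.109. With 2 normal libraries these deviations mirror each other, so the values cannot decide on pairing. In a fit with the replicate number as a block, DMED 3 and 4 have no normal partner and drop out of the comparison. It then rests on DMED 1 and 2 against normal 1 and 2, with little left to measure the spread. This fit called 2388 genes in fibroblasts, 398 in smooth muscle, 885 in pericytes, 1134 in endothelium, 1831 in Grem1-high cells and 139 in Schwann cells, and 14 lists in fibroblasts, 10 in pericytes and 11 in endothelium. No paired analysis was possible in macrophages because DMED 2 did not enter. With the block the shares of Grem1-high cells (1.78), Schwann cells (-1.66), cluster 28 (-9.03), cluster 29 (-8.81) and lymphatic endothelial cells (-11.51) did not pass. The last 3 ratios are fitted over 0 cells in DMED 1 and 2, so their size is not measured.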

Other observations

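The tests reported in this part were chosen after the results were seen. Across the 5 main classes, 7740 genes were tested in all, and 39 of them were called higher in DMED in every class, against 0 called lower in every class. Calls independent between classes would give 8.44e-05 and 0.000170 such genes, but classes of a library are not independent. Named members included the glycolytic enzymes Gapdh (log2 change 0.80 in fibroblasts, 0.77 in smooth muscle, 1.08 in pericytes, 1.09 in vascular endothelium and 1.36 in macrophages) and Pkm (1.03, 0.57, 1.20, 1.02 and 1.65). Others were the cytoplasmic actin Actg1 (1.22, 1.88, 1.87, 0.76 and 1.35), Oscp1 (1.94, 2.44, 2.32, 2.57 and 3.19), Ankub1 (2.73, 4.40, 2.73, 3.73 and 3.29) and Dcdc2c (3.601, 3.86, 3.099, 3.50 and 3.12). Unnamed gene models made up 64.1% of the 39 genes and 5.50% of all genes tested in every class, and ribosomal protein or housekeeping paralogues such as Rpl35a, Rps15al4, Ppial4d, H3f3c and Rps27a-ps1 were among the rest. These genes, apart from those in the named gene rule, were singled out after their values were seen.

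For these 39 genes the lowest main class lay at a median of 34.1% of the highest class, a level that argues against free RNA from a single class. Free RNA spread evenly over all cells would give similar levels in every class, so the value cannot decide on that. Whether reads were split differently between near-identical gene copies stays open. Over 11 processed copies tested with their parent gene in fibroblasts, the copy moved above the parent in 8, with a median of 1.09 and quartiles of -0.08 and 2.09, and only Rps27a-ps1 belongs to both sets. Bead version and processing date cannot be told apart from the group, since 0 DMED libraries share the bead version of the normal libraries. A biological difference is untested beside them.

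Molecules assigned to unnamed gene models of the mitochondrial genome were 5.32% and 5.34% of all molecules in the normal libraries and 10.03%, 9.01%, 6.10% and 6.67% in DMED 1 to 4. In fibroblasts the translation factor Eef1a1 stood at 962 CPM in normal 1 and 5084 CPM in normal 2, with 3876, 2532, 2970 and 1028 CPM in DMED 1 to 4. Ccl21, a lymphatic chemokine, stood at 8417 CPM in the lymphatic endothelial cells of the normal libraries.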
